A study of Mus musculus with 6 samples.

How the data were processed

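Gene expression was measured in type 1 conventional dendritic cells (cDC1), the dendritic cells that present antigen taken up from other cells to CD8 T cells. Per the labels' protocols, migratory cDC1 were sorted from the skin-draining lymph nodes of C57BL/6 wild-type mice as B220-negative, CD326-negative, MHC II high, CD11c intermediate, XCR1-positive, Sirpa-negative and CD40-positive cells. Total RNA was extracted on columns, and biotinylated cDNA was made from it with a kit for very small amounts of RNA before hybridisation to Affymetrix microarrays read in 1 colour. The labels give 3 unstimulated and 3 anti-CD40 stimulated samples, each on 1 array. They call the samples biological replicates without saying whether each came from separate mice, so the p-values measure only the spread between these samples, which may be partly technical. Whether the stimulation was given in the animal or in culture, at which dose and for how long, is not given in the sources used here.

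Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA, a method that corrects the background, normalises arrays to each other by quantiles and summarises the probes of a probe set. Versions and settings are not given in the sources used here. The authors deposited 1 table of intensities for 17551 probe sets on the 6 arrays, with no missing values. Its values run from 6.97 to 13701 and are therefore on a linear scale, although RMA gives logarithms, so log2 of each deposited intensity was taken before any test. Checked on the table, the higher of the 2 group geometric means was at least 20.001 for every probe set, while 2215 probe sets had an intensity under 20 on at least 1 array. This is what a filter at an intensity of 20 in either group would leave, but such a filter is named by no label used here. Genes outside this table were not analysed here.

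Probe sets were named through the platform annotation supplied with the table. There, 13963 probe sets had 1 gene symbol, 970 had several and 2618 had none, and 0 symbols needed an update through the gene identifier. Only probe sets with 1 symbol were named. For the 677 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was used, which left 12780 genes. The 3588 probe sets with several symbols or none were fitted together with all others as a check. Of these, 0 passed the threshold (83 had an unadjusted p under 0.05, and their smallest limma adjusted p was 0.335).

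The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariates, stimulated minus unstimulated). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12780 genes. A total of 35 gene lists with 755 entries was fixed in advance, covering costimulation, cytokines, chemokines, survival, antigen presentation, interferon response, metabolism, cell cycle and markers of dendritic cells and of other cell types that a lymph node sort can hold. Of the 755 entries, 514 (504 different genes) were tested. The 31 lists with at least 5 genes were tested with camera, which asks whether the members of a list rank higher or lower than the other genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the 31 lists. It was run again with the correlation estimated for each list, and beside it fry, which tests the members alone. With an estimated correlation, camera also takes its p from the 4 residual degrees of freedom of the fit. A call lost there is thus not due to correlation alone. All tests were two-sided.

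The rule for named genes was also fixed in advance. It takes up to 12 genes in each direction with the largest change among those that passed and whose groups do not overlap, or, where none passed, the 12 with the largest moderated statistic. It adds up to 4 members per list (those that passed, or else the brightest until 2 are named) and 17 fixed genes, of which 15 were measured. Predicted genes were left out. List members that passed only with adjustment over their list alone, Lgmn and Ctss as the highest and lowest class II members, and the further genes named in the closing section, were chosen after their values were seen. The alternatives set before the data were examined were another variance model, a filter on dim genes, a second normalisation, centring on medians, array weights, the replicate number as a block, leaving out each array, other probe set rules, other thresholds and a plain test without shared variance. Alternatives added after the data were seen were the interquartile range of each array as a covariate, leaving out both arrays of a replicate number and each list without its leading gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

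The procedure was tested on simulated data for this comparison over 12780 genes. With independent noise of the fitted size it recovered 25 of 100 genes changed by 1 on the log2 scale and 94 of 100 changed by 2, with 5 unchanged genes called. With the first principal component of the real arrays added to the noise it recovered 34 and 78 of 100, with 0 unchanged genes called. Camera called a list of 14 genes shifted by 0.5 in both simulations. It also called 0 unshifted lists with independent noise and 1 with the first component added. The number of arrays, 3 per group, limits the precision: the median 95% interval of a log2 difference was 1.05 wide, and an exact permutation test of 3 against 3 cannot give a p below 0.1. Genomic coordinates are left out because no genome build is named in the sources used here.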

Results

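The series set expression signatures of migratory cDC1 with and without CD40 stimulation side by side. CD40 is the receptor through which activated CD4 T cells, carrying CD40 ligand, act on dendritic cells, and an antibody against CD40 is used to engage it directly. There were 3 unstimulated and 3 anti-CD40 stimulated samples, and 12780 genes could be compared. The median deposited intensity per array lay between 51.9 and 56.3. Arrays of 1 group correlated across genes with Pearson's r between 0.915 and 0.958.

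The arrays differed in ways that the groups do not explain. The interquartile range of log2 intensities was 2.27, 1.86 and 2.02 in unstimulated replicates 1, 2 and 3, and 2.40, 1.87 and 2.15 in stimulated replicates 1, 2 and 3. The first principal component held 54.8% of the variance and had the arrays numbered 1 of both groups at one end and the arrays numbered 2 at the other. The second component held 17.3%, and its loadings were higher in the 3 stimulated arrays (-0.04 to 0.75) than in the 3 unstimulated ones (-0.39 to -0.29).

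**Figure D1:**
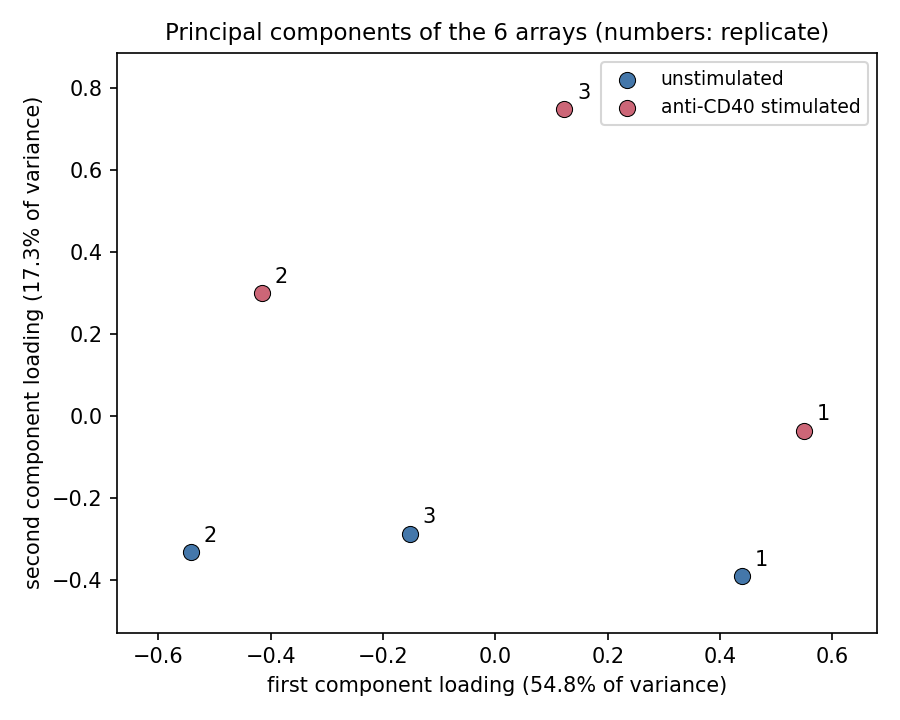
Loadings of the 6 arrays on the first component (x axis, 54.8% of the variance) and the second component (y axis, 17.3%) of the log2 intensities of 12780 genes, with colour for the group and a number for the replicate. Arrays numbered 1 lie on the right and arrays numbered 2 on the left in both groups, and stimulated arrays lie above unstimulated ones.

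Anti-CD40 stimulated cDC1 had more RNA for 2 ligands of the TNF family that costimulate T cells. Tnfsf9 encodes 4-1BB ligand, which costimulates CD8 T cells through 4-1BB, and it rose 9.15-fold (95% interval 5.96 to 14.1), from a log2 intensity of 5.69 ± 0.38 to 8.88 ± 0.35 (SD, n = 3 each). Cd70, the ligand of CD27 on T cells, rose 6.33-fold (95% interval 4.75 to 8.44), from 6.42 ± 0.09 to 9.08 ± 0.22 (SD, n = 3 each). For both genes all 3 stimulated arrays lay above all 3 unstimulated arrays. The unstimulated level of Tnfsf9 was close to the median of all genes (5.71), and background was not analysed here, so these folds are ratios of the deposited intensities and can understate the change in RNA. Their log2 differences were 3.19 ± 0.26 (SE) for Tnfsf9 (probe set 10446229, limma adjusted p = 0.0285) and 2.66 ± 0.18 (SE) for Cd70 (probe set 10452301, limma adjusted p = 0.0126).

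These 2 were the only genes past the threshold in the limma fit, with 0 genes lower. At an unadjusted p under 0.05 there were 265 genes higher and 181 lower, where evenly spread p-values over 12780 genes give 639. That number is no firm expectation here. Other splits of the 6 arrays into 3 and 3 gave 103 to 3199 such genes. The groups did not overlap for 470 genes with higher and 442 with lower stimulated values, 7.14% of all genes, where chance gives 10%. Among these, 55 were at least 2-fold higher and 25 at least 2-fold lower. The median log2 difference of all genes was 0.005. When any 1 of the 6 arrays was left out, 0 genes passed. With array weights 28 genes were higher and 18 lower, and with the interquartile range as a covariate 11 were higher and 4 lower. The replicate number as a block also gave more genes in each direction, as counted in the section on processing.

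The T cell costimulatory and coinhibitory ligands ranked higher in stimulated cells as a list. Of 19 measured members, 14 had positive and 5 negative differences, with a median log2 difference of 0.49 (camera adjusted p = 1.33e-05, and adjusted p = 0.333 with an estimated correlation of 0.03). That second run also uses fewer degrees of freedom, so the small correlation alone is not what raised its p. A split of the arrays that mixed the groups gave a smaller camera p for a list, as given in the closing section. The median was 0.18 without unstimulated replicate 2 and 0.71 without unstimulated replicate 1. Tnfsf9 and Cd70 passed over all genes and the other 17 did not. Adjusted over the list alone, 4 members were higher and 1 was lower. The 4 were Tnfsf9, Cd70, Cd86 and Cd200, and the 1 was Pdcd1lg2. Cd86, a ligand of CD28 and CTLA-4, differed by 1.54 ± 0.22 (SE), with an adjusted p of 0.00119 over the list alone and 0.208 over all genes. Cd200, the ligand of an inhibitory receptor on myeloid cells, differed by 1.05 (adjusted p 0.0219 over this list alone and 0.952 over all genes). It is also in the dendritic cell maturation list, where its adjusted p over the list alone was 0.106. Pdcd1lg2, which encodes the PD-1 ligand PD-L2, differed by -1.01 (adjusted p 0.0221 over the list alone and 0.99998 over all genes), whereas Cd274, which encodes PD-L1, differed by -0.09. Cd80, the other CD28 ligand, was bright in both groups (10.97 and 11.57) and differed by 0.60. Without Tnfsf9 the list was still called at the preset correlation (median 0.34, adjusted p = 0.00117). Without both Tnfsf9 and Cd70 the camera adjusted p of the other 17 members was 0.0343.

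**Figure D2:**
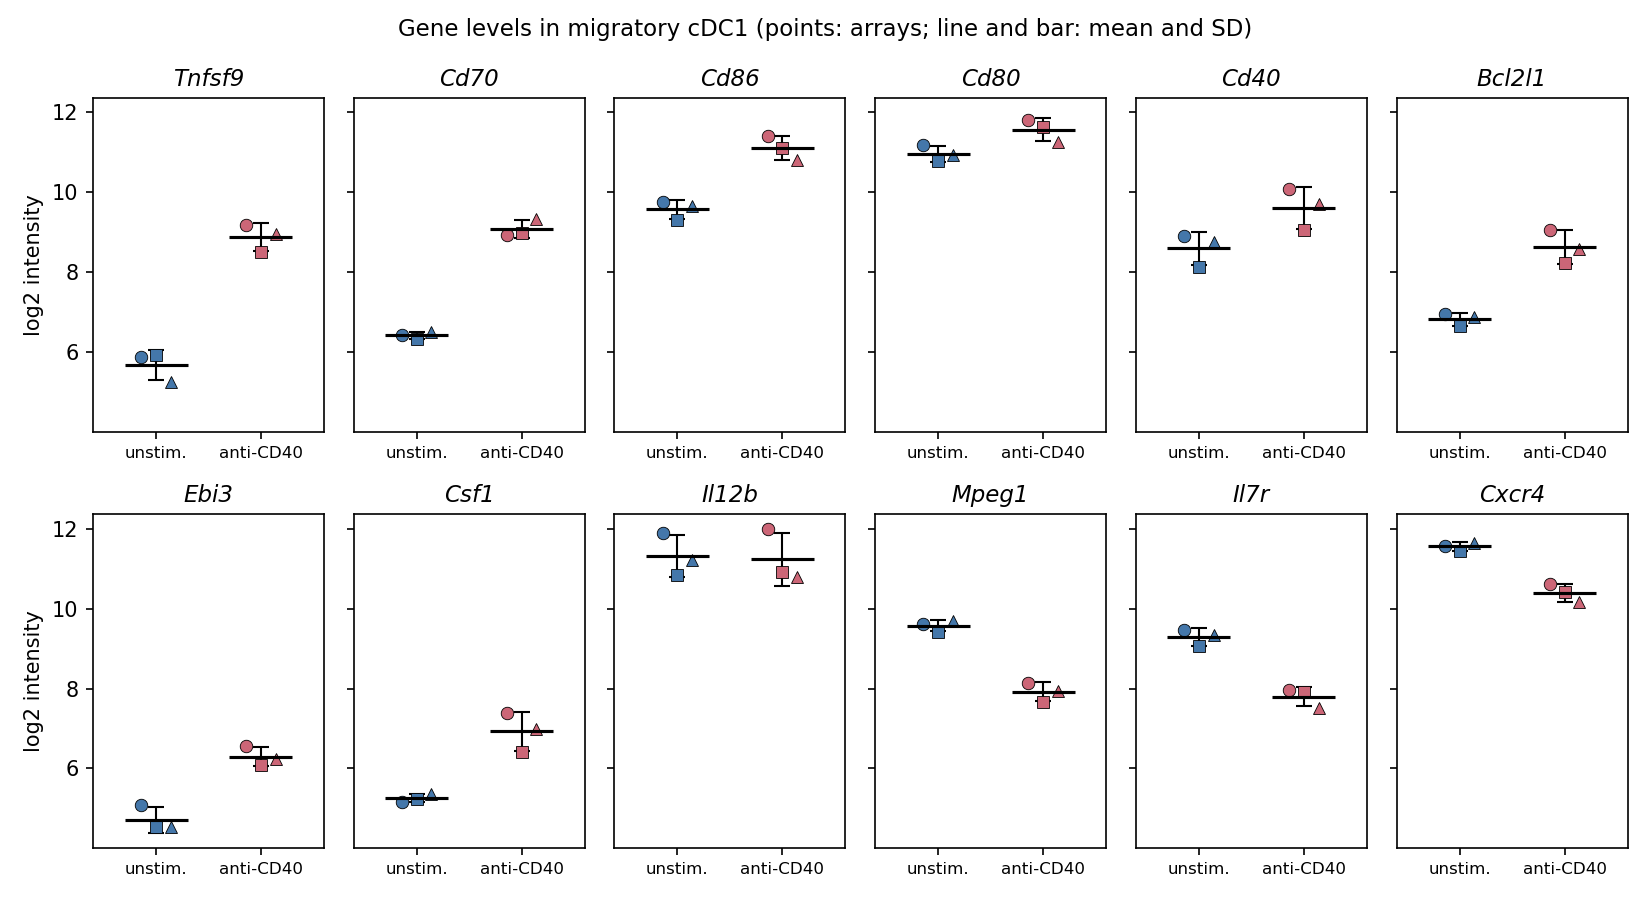
Log2 intensity (y axis) of 12 genes in unstimulated and anti-CD40 stimulated cDC1 (x axis), with 1 point per array (circle, square and triangle for replicates 1, 2 and 3) and the mean ± SD of 3 arrays in black. Tnfsf9 went from 5.69 to 8.88 and Cd70 from 6.42 to 9.08, Il12b was 11.32 and 11.23, and the other genes shown did not pass the threshold over all genes.

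Among cytokines of myeloid cells, 17 members were measured with a median difference of 0.13, and the list was called upward (camera adjusted p = 0.0343, and adjusted p = 0.375 with an estimated correlation of -0.01). That estimate is under the preset 0.01, so correlated members are not what raised this p. Over all genes 0 members passed, and over the list alone 3 were higher and 0 lower. These were Csf1, the macrophage growth factor (1.67, adjusted p over the list alone 0.00246), Ebi3, the shared subunit of IL-27 and IL-35 (1.58, 0.00246), and Il1rn, the antagonist of the IL-1 receptor (0.997, 0.00246). Il12b, which encodes the p40 subunit of IL-12 and IL-23, was among the brightest members in both groups and differed by -0.09 (95% interval -1.002 to 0.83). The other subunit of IL-27, Il27, differed by 0.20, Il6 by -0.28 and Tnf by 0.14. Without Csf1 the list had an adjusted p of 0.165. The call was lost without unstimulated replicate 1 or stimulated replicate 1 or 2, and the median ran from 0.09 to 0.20 over 17 refits, 9 of which called the list.

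The anti-apoptotic list was called upward, with a median of 0.16 over 11 members (camera adjusted p = 0.0365, and adjusted p = 0.451 with an estimated correlation of 0.06). Over all genes 0 members passed, and over the list alone 1 did. That member was Bcl2l1, which encodes the survival protein BCL-XL, at 6.82 ± 0.16 without and 8.62 ± 0.42 with stimulation (SD, n = 3 each). Its log2 difference was 1.80 ± 0.24 (SE), with an adjusted p of 0.00139 over the list alone and 0.203 over all genes. Mcl1, another survival gene of the same family, differed by 0.03, and Cflar, the inhibitor of caspase-8 activation, by 0.21. Bcl2l1 passed in 3 of 16 refits without a block, with adjusted p values from 0.00893 to 0.99999. With the replicate block, a pairing that the labels do not give, its limma adjusted p was 0.00812. Without Bcl2l1 the adjusted p of the list was 0.341. The list was called in 6 of 17 refits, with medians from 0.07 to 0.36, and lost its call without replicate 1 or 3 of either group. The pro-apoptotic list, with 18 members, had a median of 0.01 and was not called.

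A list of the dendritic cell maturation and migration program (23 members, median 0.22, camera adjusted p = 0.0343), one of antigen uptake and scavenger receptors (11 members, median 0.35, 0.0343) and one of cholesterol synthesis and uptake (18 members, median 0.15, 0.0443) were also called upward. With an estimated correlation (0.34, -0.06 and 0.11) the adjusted p values were 0.918, 0.375 and 0.604. The median difference between arrays numbered 1 and 2 was 0.65 in unstimulated and 0.81 in stimulated cells for the maturation list, -0.05 and -0.11 for antigen uptake, and 0.40 and 0.25 for cholesterol. The median of the antigen uptake list was 0.06 without stimulated replicate 3, and that of the maturation list 0.07 without unstimulated replicate 2. In all 3 lists 0 members passed, over all genes or over the list alone. Ccr7, the receptor that guides dendritic cells to lymph nodes, was at 12.51 and 12.66 and differed by 0.15. Fscn1, which bundles actin in mature dendritic cells, differed by 0.83. Clec7a, the beta-glucan receptor Dectin-1, differed by 0.57, and Itgav, the integrin alpha V chain, by 0.81. The isoprenoid enzyme gene Idi1 differed by 0.90, Fdps by 0.64 and Sqle by -0.42. Without their leading genes (Cd200, Itgav and Idi1) these lists had adjusted p values of 0.153, 0.153 and 0.165. They were called in 10, 8 and 5 of 17 refits, and leaving out 1 array lost the call for 2, 4 and 4 of the 6 arrays.

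Chemokine receptors were the 1 list called downward, with 8 members measured and a median of -0.13 (camera adjusted p = 0.0343, and adjusted p = 0.375 with an estimated correlation of 0.03). Over the list alone 1 member was lower, Cxcr4, the receptor of CXCL12, at 11.56 ± 0.11 and 10.39 ± 0.22 (SD, n = 3 each). It differed by -1.17 ± 0.18 (SE), with an adjusted p of 0.00235 over the list alone and 0.209 over all genes. Without Cxcr4 the adjusted p of the list was 0.341. The list was called in 6 of 17 refits, with medians from -0.31 to -0.07, and lost its call without unstimulated replicate 1 or 3 or stimulated replicate 1 or 2. Among the 16 chemokines, whose list was not called (median -0.07), Cxcl1, which attracts neutrophils, differed by 1.26 (adjusted p over the list alone 0.00706). The T cell attractants Ccl17 and Ccl22 differed by 0.50 and 0.23.

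**Figure D3:**
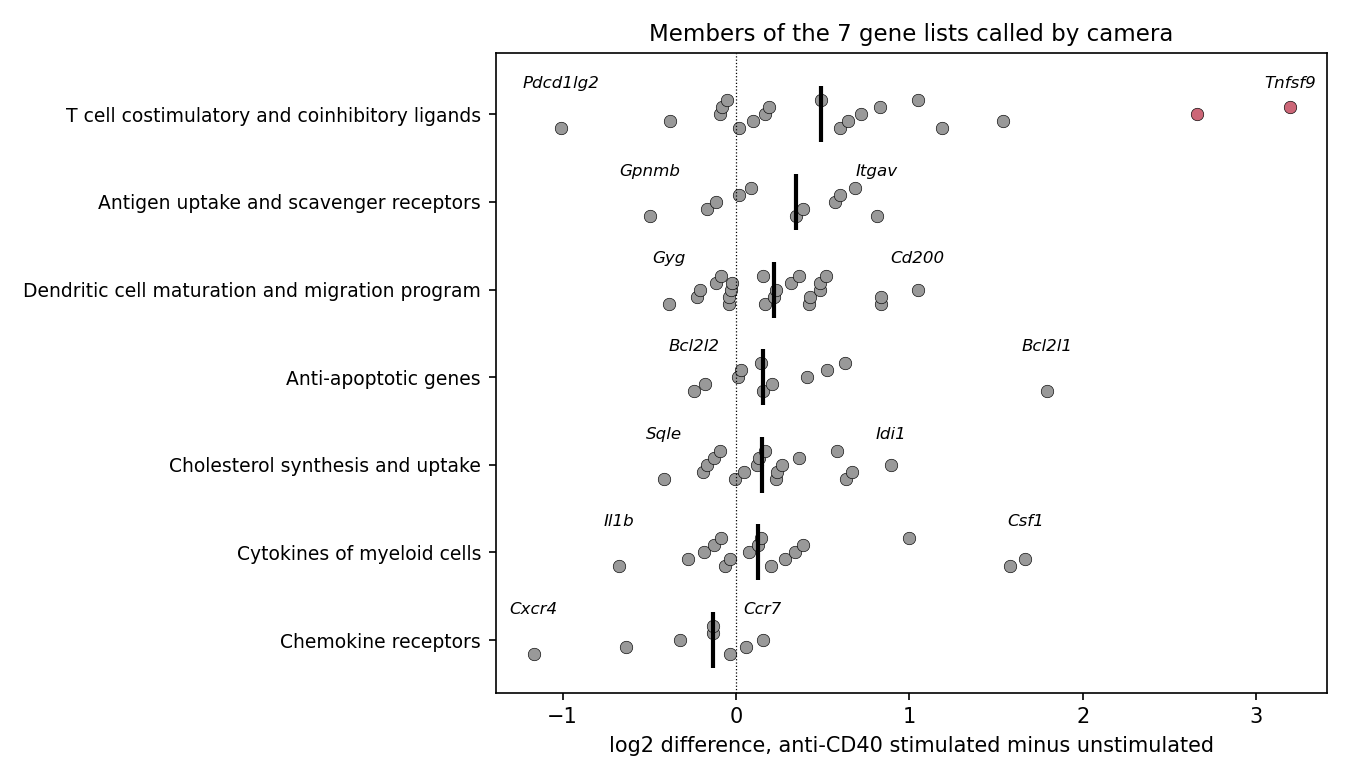
Log2 difference, stimulated minus unstimulated (x axis), of each measured member (points) of the 7 lists called by camera (y axis), with a black bar at the median of the list, coloured points for genes past the threshold over all genes and names for the lowest and highest member. The medians run from -0.13 for chemokine receptors to 0.49 for costimulatory and coinhibitory ligands, and 2 points, Cd70 and Tnfsf9, are past the threshold.

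In the lower direction 0 genes passed, and the smallest adjusted p was 0.144. The rule then names the 12 genes with the largest statistic, all of which had stimulated values below every unstimulated value. Mpeg1, which encodes the pore-forming protein perforin-2 of phagocytes, was at 9.58 ± 0.14 and 7.92 ± 0.24 (SD, n = 3 each) and differed by -1.66 ± 0.19 (SE, adjusted p = 0.144). It passed in 4 of 16 refits without a block, with adjusted p values from 0.00558 to 0.99999. With the replicate block, a pairing that the labels do not give, its limma adjusted p was 0.00812. Il7r, the alpha chain of the IL-7 receptor, differed by -1.50 ± 0.20 (SE, adjusted p = 0.203). Pla2g7, which encodes a secreted phospholipase that degrades platelet-activating factor, differed by -2.04, F5, which encodes coagulation factor V, by -1.76, and Lpar6, a receptor of lysophosphatidic acid, by -1.30. Cxcr4 was also among the 12. The others were Spata32 (-1.93), Plekhs1 (-1.90), Gapt (-1.24), Sh2d4b (-0.99), the chromatin remodeller gene Hells (-0.96) and Trim7 (-0.95).

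The fixed genes of the sort and of cDC1 identity had no member past the threshold. Cd40 itself, on which all cells were sorted, was at 8.60 ± 0.41 and 9.61 ± 0.52 (SD, n = 3 each) and differed by 1.01 (95% interval 0.26 to 1.76, adjusted p over all genes 0.99998). Xcr1, the chemokine receptor on which the cells were sorted, was dim (4.44 and 4.67) and differed by 0.24. Sirpa, used to exclude other dendritic cells, was at 4.67 and 4.83 and differed by 0.15. At such low levels, with background not analysed here, the small differences of Xcr1 and Sirpa say little about cDC1 identity. Epcam, which encodes the excluded marker CD326, differed by 0.57 from a dim 4.74, Itgae, the CD103 chain, by 0.17 and Ptprc, which encodes CD45 and its B220 form, by -0.19. The transcription factor genes Irf8 and Batf3, needed for cDC1 development, differed by 0.64 and 0.40 with intervals that held 0 (-0.59 to 1.86, and -0.47 to 1.28). Clec9a, a receptor for dead cells, differed by -0.26. The list of cDC1 identity genes (19 measured) had a median of 0.17 and was not called.

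Of the 31 lists tested, 24 were not called by camera, with adjusted p values from 0.0625 to 0.997, and 0 of their members passed over all genes. Signalling and response lists had medians of -0.003 for NF-kB subunits, inhibitors and adaptors, 0.03 for the TNF receptor superfamily, -0.06 for Toll-like receptors and innate sensing adaptors, -0.08 for the type I interferon response and -0.08 for the interferon gamma response. Medians were 0.14 for MHC class I antigen processing and 0.05 for MHC class II antigen presentation. Members of the class II list differed in both directions: the protease gene Lgmn by 0.83 (95% interval -0.13 to 1.79), the invariant chain gene Cd74 by -0.78 (-1.40 to -0.15) and the cathepsin S gene Ctss by -0.78 (-1.28 to -0.29). The groups did not overlap for Ctss, and the adjusted p over the list alone was 0.109 for Ctss and 0.162 for Cd74. H2-Aa, an MHC class II chain, was at 12.55 in both groups. S phase and mitosis genes had a median of 0.10 and the lowest p of these lists, 0.0625, and their 1 member past the threshold over the list alone was Mki67, which encodes the proliferation marker Ki-67 (2.26 ± 0.34 SE, adjusted p 0.00547 over the list alone and 0.208 over all genes). Metabolic and housekeeping lists had medians of 0.05 for glycolysis, 0.12 for oxidative phosphorylation, 0.05 for the unfolded protein response, 0.09 for immediate early and dissociation stress genes, 0.06 for ribosome biogenesis and -0.01 for cytosolic ribosomal proteins.

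Markers of other cells had medians of 0.05 for B cells, 0.17 for T cells, 0.31 for cDC2, -0.12 for monocytes and macrophages, 0.03 for plasmacytoid dendritic cells, -0.06 for keratinocytes and -0.15 for fibroblasts and endothelium. Lists with fewer than 5 measured genes were not tested, and their medians were -0.30 for NK and cytotoxic cells (3 genes), 0.06 for Langerhans cells (3), -0.12 for neutrophils (2) and -0.11 for erythroid cells (4). The B and T cell markers were dim in both groups: the brightest were Ighm, the IgM heavy chain, at 5.47 and 5.30, and the T cell surface gene Cd5 at 5.67 and 5.78. The median and the direction of the camera test differed in sign for NF-kB, pro-apoptotic, unfolded protein response, B cell, monocyte and macrophage, and plasmacytoid dendritic cell lists. The mean of the members was 0.07 for NF-kB genes, -0.005 for the unfolded protein response and 0.08 for monocytes and macrophages, each opposite in sign to its median.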

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

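Tnfsf9 and Cd70 kept their direction in all 17 refits of the model, with log2 differences of 2.94 to 3.57 and 2.54 to 2.74. Both passed in the 8 refits that use all 6 arrays and in none of the 9 that leave arrays out, where fewer samples are fitted and adjusted p values reached 0.99988. Leaving out 1 array at a time gave 0 genes higher and 0 lower in every case, and 3 to 6 called lists. The main counts were 2 genes higher, 0 lower and 7 lists. Quantile normalisation once more gave 5 higher, 1 lower and 3 lists; centring on medians gave 3 higher, 1 lower and 6 lists; array weights gave 28 higher, 18 lower and 2 lists; a filter on the dimmest genes (the lowest of 3 equal parts) gave 2 higher, 0 lower and 2 lists. An adjusted p under 0.01 and a plain test without shared variance each gave 0 genes higher. With the interquartile range of each array as a covariate, chosen after seeing the data, there were 11 higher, 4 lower and 1 list. Without both arrays numbered 1, 2 or 3, also chosen after seeing the data, 0 genes were higher and 0 lower, and the lists numbered 1, 7 and 5. The costimulatory list passed in all 17 refits at the preset correlation, with medians of 0.18 to 0.71, and the other called lists in 5 to 10 of them, with medians of 0.06 to 0.57 for antigen uptake, 0.07 to 0.38 for maturation, 0.07 to 0.36 for anti-apoptotic genes, 0.10 to 0.27 for cholesterol, 0.09 to 0.20 for cytokines and -0.31 to -0.07 for chemokine receptors. Camera with an estimated correlation and fry in 1 direction called 0 lists. Fry in either direction called 7, but not the same 7 as camera. It called the S phase and mitosis genes (fry adjusted p = 1.58e-05) and the cDC2 markers (0.000644). It did not call the maturation list (0.883) or the cholesterol list (0.307). Without the leading gene of each list, a choice made after seeing the data, camera called 1. The cause of the other shifts was not tested. Groups share replicate numbers in the labels, which give no pairing. The deviations from the group means correlated at 0.73, 0.59 and 0.06 for numbers 1, 2 and 3. Unstimulated replicate 3 correlated better with stimulated replicate 2 (0.19), so the numbers were not taken as pairs. Arrays numbered 3 lay near the middle of the first component, so their low correlation cannot exclude pairs. With the replicate block 30 genes were higher, 8 lower and 2 lists called. For the 101 named genes, 1706 refitted values were compared: 58 newly passed, 18 (those of Tnfsf9 and Cd70 with arrays left out) no longer passed and 0 values called in either fit changed sign. Another 125 values that passed in no fit changed sign, in 36 genes with a main difference of at most 0.29. Background signal was not analysed here, so limits from dim probe sets were examined only through the filter on dim genes.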

Other observations

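The tests on B cell markers, T cell markers, cell cycle genes and the array structure behind Cd70 and Tnfsf9 below were chosen only after the values they measure were seen, and the bound against the cell cycle explanation was made stricter after its test had run; the other tests were set before their result was seen. Below the threshold, several genes chosen after their values were seen differed more than 2-fold with stimulated values above every unstimulated value. Among the 12 genes with the largest upward statistic after Tnfsf9 and Cd70 were Cd81, a tetraspanin of the cell surface (2.04 ± 0.24, SE), Csrp2, a LIM domain protein gene (1.64), Rhob, a small GTPase gene (1.55), Ptgs2, which encodes the prostaglandin synthase COX-2 (2.65), Hspa2, a heat shock protein gene (2.07), Spred2, an inhibitor of MAP kinase signalling (1.67), and Ube2l6, the conjugating enzyme for ISG15 (1.10). Their limma adjusted p values lay between 0.144 and 0.245. Cd82, another tetraspanin, differed by 2.95 ± 0.62 (SE, adjusted p = 0.562) and Jag1, a Notch ligand, by 2.44 ± 0.69 (SE, adjusted p = 0.99998). Among 16 refits without a block, Cd81 passed in 4 (adjusted p 0.00558 to 0.99999), Cd82 in 2 (0.00779 to 0.99999) and Jag1 in 1 (0.0231 to 0.99999). With the replicate block, a pairing that the labels do not give, the limma adjusted p values of Cd81, Cd82 and Jag1 were 0.00812, 0.00178 and 0.0070.

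Whether the families of these genes moved with them was tested with lists written after Cd81, Cd82 and Jag1 had been seen. The other 15 measured tetraspanins had a median difference of 0.07. The other 19 measured Notch ligands, receptors and targets had a median of -0.04. Camera without Cd81, Cd82 and Jag1, adjusted over the 2 families, gave adjusted p values of 0.782 for tetraspanins and 0.792 for Notch genes, so neither family passed as a group. That adjustment was added after the unadjusted results, which did not pass at 0.05 either, had been seen.

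The largest structure of the data set arrays numbered 1 apart from arrays numbered 2 in both groups, with arrays numbered 3 on either side of the middle (-0.15 and 0.12): between numbers 1 and 2, the log2 difference correlated across genes between the groups (Pearson's r 0.737; genes are not independent replicates), with 787 genes at least 2-fold higher and 81 at least 2-fold lower in number 1 in both groups. Genes higher in number 1 included the phosphatase gene Ppp4c (4.03 and 3.01 in unstimulated and stimulated cells) and the actin-bundling gene Fscn1 (2.45 and 2.004), while the calcium-binding protein gene S100a4 (-1.35 and -1.69) and the respiratory chain gene Cox7b (-1.44 and -1.36) were lower. An unequal spread of intensities does not account for the whole of it, because after quantile normalisation the first component still held 48.4% of the variance, from 54.8% before. A bias with length remains open: the rank correlation of the difference with gene span, within deciles of intensity, was 0.171 in unstimulated and 0.203 in stimulated cells, which is weak, and gene span is only a rough stand-in for transcript length. RNA quality, input amount and a true difference between cell preparations may each play a part and were not tested.

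The same structure bears on the counts. Of the 10 splits of the 6 arrays into 3 and 3, 2 gave at least as many called genes as the real split, itself included: the real split called 2 genes and the highest other called 698. That split set both arrays numbered 1 and stimulated replicate 3 against the others, which are the sides of the first component, so it points to the structure of the samples. For lists, only the real split itself reached the count of 7. The other splits called 5, 3, 0, 2, 1, 3, 6, 5 and 0 lists, so most splits that mixed the groups also called lists at the preset correlation. The smallest unadjusted camera p of any list was 4.28e-07 in the real split. It was 2.7e-07 with unstimulated replicate 1 and stimulated replicates 1 and 2 set against the others. A list p of this size thus also arose in a split that mixed the groups. With 10 splits the share can never fall below 0.1, which is too few for a share under 0.05.

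For the rise of Cd70 and Tnfsf9, RNA from activated B or T cells in the sorted cells was weighed, since such cells can carry both ligands. The 6 measured B cell markers had a median difference of 0.052 and none above 0.27, and the 11 T cell markers a median of 0.17 and none above 0.83, whereas the genes themselves rose by 2.66 and 3.19. None of these markers is in another list and 0 of them were above the median intensity of unstimulated cells. Their median levels there were 5.10 for B and 4.68 for T cell markers. Differences at such low levels can understate a change in RNA, so the markers cannot exclude a small share of such cells. The table held only 6 of 17 listed B cell markers and 11 of 19 T cell markers. The gate on B220, XCR1 and MHC II is meant to remove such cells, but the purity of the sort was not tested here. Other dendritic cells were not weighed. The cDC2 markers had a median difference of 0.31, and their list was not called by camera but was by fry in either direction (adjusted p = 0.000644). The smaller of the differences was 2.61 after quantile normalisation and 2.66 with the interquartile range of each array as a covariate. Both genes still passed each time, and the covariate took Jag1 from 2.44 to 2.09. Over the tested genes this range was alike in unstimulated (2.19, 1.74 and 1.92) and stimulated arrays (2.31, 1.75 and 2.03). Adjusting for it could therefore move a group difference little. The differences did not depend on these adjustments, which decide little about the first component as a cause. A response of the cDC1 to CD40 and effects of handling that differ between the groups stay open, and no test here separates them.

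Mki67 differed by 2.26 ± 0.34 (SE), and more cells in S phase or mitosis may be a source. Fry in either direction called the S phase and mitosis list with Mki67 in it (adjusted p = 1.58e-05), and camera did not. The other 20 measured cell cycle genes had a median difference of 0.075, with 3 higher and 0 lower at an unadjusted p under 0.05, among them the replication genes Uhrf1 (1.03) and Cdc6 (0.76) and the mitotic kinase gene Cdk1 (0.66). Members went both ways, with Mcm6 at -0.44 and Tk1 at -0.29, so the median does not decide, and a change in cycling and a change in Mki67 by itself cannot be told apart here. Cells of another kind that divide in the lymph node were not tested beyond the markers above.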
